A study of Mus musculus with 47 samples.

How the data were processed

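Gene expression was measured in primary B cell lymphoma cells of mice that carry a Myc transgene driven by the immunoglobulin heavy chain enhancer (Eµ-myc). Per the labels' protocols, the cells were taken from lymph nodes, transduced with a retrovirus carrying the antiapoptotic gene Bcl2, selected with puromycin for 48 h and grown on NIH 3T3 mouse fibroblasts that had received 20 Gy of gamma irradiation. ADR cultures received 0.05 µg/ml Adriamycin (doxorubicin, a DNA-damaging drug) for 5 days. Total RNA (3 µg) was labelled by a one-cycle 3′ protocol and hybridised to Affymetrix arrays.

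The deposited values are log2 expression levels per probe set that the authors made with RMA and the oligo package in R 3.5.0, per the submitters' processing notes. Whether the 47 arrays were processed together, and whether any batch step followed, is not given in the sources used here. Per the labels, each array holds 1 culture of 1 lymphoma under 1 treatment, and the 47 arrays come from 22 cultures. The table has 45101 probe sets. Of these, 34958 carry 1 gene symbol in the platform annotation, 932 carry several and 9211 are unnamed here. Symbols of 34754 probe sets were updated through their Entrez gene number. Each gene was represented by the probe set with the highest mean over all 47 arrays, which gave 18194 genes. No filter was set on dim genes. Values ran from 0.308 to 15 and array medians from 4.07 to 4.43. The number of arrays limits the precision. Detection calls and scan dates were not used here, so limits from signal level or scan batch were not assessed.

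Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8) for reading. For the comparisons within a culture, all 47 arrays entered a single fit with the 22 cultures as fixed blocks and 4 treatment terms. The series design text describes matched pairs, which is where the pairing comes from. As a check, the 2 arrays of a culture were compared by the correlation of their deviations from their group means. It was above 0.1 in 10 of 14 WT pairs, in 5 of 5 Suv39h1- pairs and in 2 of 9 Suv39h1ER pairs. The genotypes were compared before and after treatment over 19 arrays each, with no block because each lymphoma entered once. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Replicates are separate lymphomas by their numbers in the labels, which the expression values leave open for the 3 Suv39h1ER cultures, for WT 2949, 5043, 5766 and 6054 and for Suv39h1- 7890 and 9250. Signs of RNA quality (the 18S control signal and the 3′ minus 5′ differences of Gapdh and Actb) were compared in 7 comparisons by exact permutation of genotypes or exact sign changes within cultures, adjusted over these 21 tests.

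A total of 31 gene lists with 691 members, 636 of them measured, were fixed before the data were examined. They cover replication, mitosis, dna repair, p53 targets, senescence arrest and nuclear lamina, senescence-associated secretory factors, NF-kB, interferon, lysosome, autophagy, unfolded protein and integrated stress, glycolysis, oxidative phosphorylation, cholesterol synthesis, Myc targets and ribosome biogenesis, H3K9 methylation and heterochromatin, polycomb, Wnt and stem cell genes, antigen presentation class I and class II, the Bcl2 family, B cell identity, precursor B cells, plasma cells, and markers of fibroblasts, T cells, NK cells, macrophages and monocytes, neutrophils, erythroid cells and endothelium. A list's value is the mean log2 change of its members, with the SD over lymphomas. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation between genes was run beside it. No list call of any comparison held with the estimated correlation. The list response of WT and Suv39h1- lymphomas was also compared by an exact permutation test over all 11628 splits of the 19 lymphomas. Relations across the 14 WT lymphomas were tested with 100000 resamples.

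The genes named per comparison follow a rule fixed before the data were examined. They are up to 6 rising and 6 falling genes with the largest change among called genes that moved the same way in every pair (in at least 12 pairs for WT), the 3 members of each list with the smallest p, and Bcl2, Myc, Cdkn1a, Cdkn2a, Mki67 and Lmnb1. Probe sets naming Suv39h1 or Trp53 alone were not analysed here, so the genotype labels were not checked by the targeted gene.

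The fit was tested on simulated data in which 200 of 18194 genes were changed, with normal noise independent between genes and of equal spread in all groups. For a log2 change of 1 it recovered 67 of 67 genes for WT ADR vs native, 79.1% for Suv39h1- ADR vs native, 70.1% for the difference between both responses, 73.1% for Suv39h1ER ADR 4OHT vs ADR, 74.6% for Suv39h1ER ADR vs native, 73.1% for Suv39h1ER ADR 4OHT vs native, 83.6% for the native comparison of genotypes and 80.6% for that after ADR. For a log2 change of 0.5 the shares, in the same order, were 71.6%, 37.3%, 11.9%, 14.9%, 8.96%, 8.96%, 35.8% and 32.8%, and for a change of 2 they lay between 90.9% and 98.5%. The simulated fits called 118 to 193 genes. The adjusted threshold is stricter where fewer genes pass, as with the 2, 62, 26 and 23 real calls of some comparisons. The shares are too high for those and do not show that an uncalled gene was unchanged.

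Alternatives set before the data were examined were fits without the block, with the block as a random effect (for the comparisons of genotypes, all 47 arrays in 1 fit with the lymphoma as a random effect), with equal culture numbers of different genotype labels as 1 block, and with the compared groups alone. Others used the mean of a gene's probe sets, every probe set, genes with a mean level above the median, repeated quantile normalization, median centring, eBayes with trend and robust, array weights, and each lymphoma left out in turn. Added after seeing the data were fits without 2 Suv39h1ER arrays that did not match their culture, with SuvER-5043 as the single Suv39h1ER culture (1 array per arm, assumed to vary like the WT and Suv39h1- arrays), with WT and Suv39h1- arrays alone, with the fibroblast list change as a covariate, and with lymphomas alike over the marking probe sets averaged and counted once. Lymphomas were alike where the lowest of the correlations between their arrays exceeded the lowest between both arrays of 1 lymphoma, the latter scored with probe sets chosen without that lymphoma.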

Results

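RNA levels were measured on 47 arrays of Eµ-myc;Bcl2 lymphoma cells, a mouse model of aggressive B cell lymphoma in which Bcl2 blocks apoptosis. The histone methyltransferase Suv39h1, which places the H3K9me3 mark of silenced chromatin, was present in 14 lymphomas (WT) and deficient in 5 (Suv39h1-). Each was measured untreated (native) and after 5 days of ADR. A further 3 cultures (Suv39h1ER) were Suv39h1-deficient and carried a Suv39h1 fused to the estrogen receptor domain, whose activity depends on the ligand 4-hydroxytamoxifen (4OHT). These were measured native, under ADR, and under ADR with 4OHT. The labels call WT cells under ADR and Suv39h1ER cells under ADR with 4OHT senescent, and all other arrays non-senescent. Array medians lay between 4.32 and 4.43 on the log2 scale except for the array of Suv39h1- lymphoma 1032 under ADR, at 4.07. Over 200 probe sets that mark a lymphoma, the arrays of WT lymphomas 2949, 5043, 5766 and 6054 correlated with each other at 0.556 to 0.924, and those of Suv39h1- lymphomas 7890 and 9250 at 0.734 to 0.753, where both arrays of 1 lymphoma had at least 0.469 and a median of 0.751. For the latter the probe sets were chosen without that lymphoma, and for the former with all of them, which can raise the former. Over 46 immunoglobulin V, Xist and Y-linked probe sets, arrays of 1 WT or Suv39h1- lymphoma had a median Spearman correlation of 0.954 and a lowest of 0.886. Arrays under different lymphoma labels had a median of 0.845 and a highest of 0.976. These values leave open whether the 4 and the 2 are separate lymphomas, so n = 14 and n = 5 count lymphomas as labelled, and SDs and p-values are too small if a lymphoma entered more than once. Counting each such set once, an alternative added after seeing the data, left 11 WT and 4 Suv39h1- lymphomas.

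Myc and Bcl2 are the genes introduced in this model, and whether the probe sets read the introduced copies was not tested. Myc had a mean log2 level of 11.3 ± 0.39 (SD, n = 14) in native WT and 11.2 ± 1.08 (SD, n = 5) in native Suv39h1- cells. The brightest Bcl2 probe set stood at 11.22 ± 0.44 (SD, n = 14) in native WT, 9.04 ± 0.78 (SD, n = 5) in native Suv39h1- and 9.81 ± 0.95 (SD, n = 3) in native Suv39h1ER cells. The other 4 Bcl2 probe sets had native WT means of 6.66, 5.37, 3.38 and 3.19, beside 6.29, 5.00, 3.30 and 3.04 in native Suv39h1- cells.

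**Figure D1:**
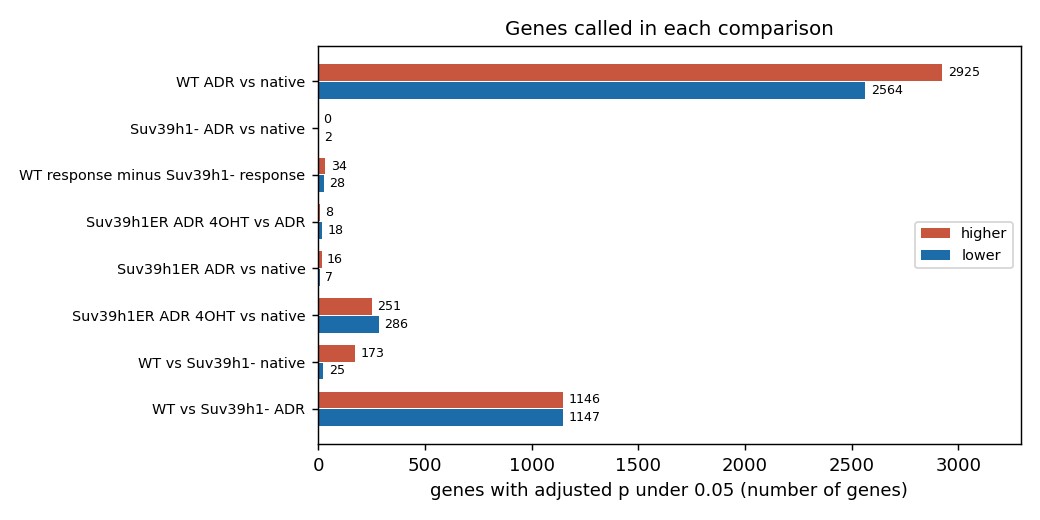
Number of genes (horizontal axis) with an adjusted p under 0.05 in each of 8 comparisons, higher (red) and lower (blue) in the first-named group. ADR called 5489 genes in the 14 WT lymphomas and 2 in the 5 Suv39h1- lymphomas.

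The first comparison asked how senescence-competent lymphomas respond to ADR. In the arrays of the 14 WT lymphomas, RNA of the cell division machinery was lower under ADR. RNA of secreted factors, lysosomal genes, interferon-stimulated genes and p53 targets was higher, together with markers of fibroblasts and macrophages. The largest component of variation among the arrays held 30.3% of the variance. It correlated at 0.921 with the fibroblast list and at -0.63 with the mitosis list. With fibroblast and macrophage changes both in the model, the secretory value was 0.216 (95% interval -0.188 to 0.619). Which cells the secretory rise came from therefore stays open. A total of 5489 of 18194 genes changed, 2925 higher and 2564 lower, and 977 changed by at least 1 log2 unit. Kif11, the motor that separates spindle poles, had the largest fall of all genes tested, with a log2 change of -2.72 (SE 0.28, adjusted p = 1.28e-07, lower in 14 of 14 lymphomas). The chemokine Cxcl5 had the largest rise, at 3.78 (SE 0.56, adjusted p = 1.19e-05, higher in 14 of 14).

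All 3 proliferation lists fell. Of 35 measured mitosis genes 34 were lower, also 34 adjusted over the list alone, and the list mean was -1.91 ± 0.88 (SD, n = 14). Aurkb, a kinase of chromosome segregation, fell by 2.52, the cyclins Ccnb2 and Ccna2 by 2.49 and 2.37, the spindle protein Spag5 by 2.38, the mitotic kinase Plk1 by 2.09, the checkpoint kinase Bub1b by 2.23 and the proliferation marker Mki67 by 2.31 (SE 0.24). The cohesin acetyltransferase Esco2 fell by 2.38. Of 35 replication genes 34 were lower, 35 adjusted over the list alone, with a list mean of -1.25 ± 0.55 (SD, n = 14). Gins1, part of the replicative helicase, fell by 1.78. The DNA polymerase subunit Pola1 fell by 1.99 on 1 probe set and stood at 0.00 on the other. All 17 dna repair genes were lower, also 17 adjusted over the list alone (mean -1.31 ± 0.54, SD, n = 14), among them Fancd2 at -1.86 and the checkpoint kinase Chek1 at -1.58. The camera test gave adjusted p = 5.40e-32 for mitosis, 1.34e-28 for replication and 5.63e-17 for dna repair, and for each of them adjusted p = 0.0803 with an estimated correlation.

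Targets of p53 rose in 17 of 28 members, with 19 higher and 1 lower adjusted over the list alone, and the list mean was 0.56 ± 0.53 (SD, n = 14), above 0 in 11 of 14 lymphomas (adjusted p = 1.11e-05, and adjusted p = 0.277 with an estimated correlation). Phlda3 rose by 1.72, Mdm2, which targets p53 for degradation, by 1.26, and the cell cycle inhibitor Cdkn1a (p21) by 1.11 (SE 0.20, higher in 13 of 14). Cdkn2a, which codes for p16 and Arf, had a log2 change of 0.01 (SE 0.45, adjusted p = 0.989). The list of senescence arrest and nuclear lamina genes had 5 of 14 members higher and 5 lower, as also adjusted over the list alone, with a mean of -0.15, a median of 0.08 and adjusted p = 0.777. Its falling members included the lamin Lmnb1, at -1.62, and the chromatin protein Hmgb2, at -1.998, both used as markers lost in senescent cells.

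The senescence-associated secretory list rose in 28 of 39 members and fell in 1, with 29 and 1 adjusted over the list alone. Its mean was 1.16 ± 0.53 (SD, n = 14) and above 0 in 14 of 14 lymphomas (adjusted p = 4.50e-12, and adjusted p = 0.0803 with an estimated correlation). The monocyte attractant Ccl2 rose by 2.91, the neutrophil attractant Cxcl2 by 2.90 and the collagenase Mmp13 by 2.97. The list change was larger where fibroblast markers rose more, with a slope of 0.32 (95% interval 0.195 to 0.449) per log2 unit of the fibroblast list over the 14 lymphomas. NF-kB genes rose in 12 of 18 members, 13 adjusted over the list alone, with a mean of 0.61 (adjusted p = 6.16e-06, and adjusted p = 0.174 with an estimated correlation). Interferon-stimulated genes rose in 23 of 27 members, also 23 adjusted over the list alone, with a mean of 0.99 ± 0.80 (SD, n = 14; adjusted p = 3.01e-10, and adjusted p = 0.190 with an estimated correlation). Among them Oasl2 rose by 2.07 and Zbp1, a sensor of nucleic acids, by 1.38.

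Lysosomal genes rose in 26 of 29 members, 28 adjusted over the list alone, with a mean of 0.84 ± 0.41 (SD, n = 14), above 0 in 14 of 14 lymphomas (adjusted p = 5.07e-19, and adjusted p = 0.0803 with an estimated correlation). The membrane protein Lamp1 rose by 1.10 and the peptidase Tpp1 by 1.15. This list too moved with the fibroblast markers, with a slope of 0.19 (95% interval 0.0458 to 0.335). Autophagy genes rose in 13 of 23 members and fell in 1, as also adjusted over the list alone (mean 0.33, adjusted p = 6.59e-05, and adjusted p = 0.0978 with an estimated correlation), led by the cargo receptor Sqstm1 (p62) at 1.29. Stress genes of the unfolded protein and integrated stress list rose in 9 of 23 members, 11 adjusted over the list alone (mean 0.34, adjusted p = 0.00107, and adjusted p = 0.356 with an estimated correlation).

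Metabolic and growth lists fell. Cholesterol synthesis genes fell in 13 of 16 members, 16 adjusted over the list alone, with a mean of -0.84 (adjusted p = 1.51e-09, and adjusted p = 0.166 with an estimated correlation). The sterol carrier Stard4 fell by 1.40, the squalene epoxidase Sqle by 1.01 and the sterol regulator Srebf2 by 1.01. Oxidative phosphorylation genes fell in 16 of 25 members, 17 adjusted over the list alone (mean -0.22, adjusted p = 1.19e-07, and adjusted p = 0.127 with an estimated correlation), with Uqcrfs1 of complex III at -0.59. Glycolysis genes fell in 7 of 18 members, with 1 higher and 8 lower adjusted over the list alone (mean -0.31, adjusted p = 0.00403, and adjusted p = 0.373 with an estimated correlation), with the kinase Pdk1 at -0.996. Myc targets and ribosome biogenesis genes fell in 13 of 31 members, also 13 adjusted over the list alone (mean -0.31, adjusted p = 2.51e-05, and adjusted p = 0.426 with an estimated correlation), and Myc itself fell by 0.78 (SE 0.16). With the fibroblast list change as a covariate, the Myc target list passed in the opposite direction, with a mean of 0.37 (camera, adjusted p = 1.61e-05), and Myc was at 0.12 (limma, adjusted p = 0.812). Both are fitted values at a fibroblast list change of 0, the low end of its range.

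H3K9 methylation and heterochromatin genes fell in 12 of 26 members and rose in 1, with 15 and 1 adjusted over the list alone (mean -0.24 ± 0.11, SD, n = 14; adjusted p = 6.79e-06, and adjusted p = 0.0803 with an estimated correlation). The falling members included the heterochromatin protein Cbx5 (HP1α), at -1.26, and the DNA methyltransferase Dnmt1, at -1.14, whereas the architectural protein Hmga2 rose by 2.98. Polycomb genes fell in 7 of 15 members and rose in 2, with 7 and 3 adjusted over the list alone (mean -0.27, adjusted p = 0.0110, and adjusted p = 0.277 with an estimated correlation), with the methyltransferase Ezh2 at -1.26. The Wnt and stem cell list did not pass (mean 0.17, adjusted p = 0.210), with 9 of 30 members higher and 4 lower, as also adjusted over the list alone. Klf4 rose by 2.61 and the adhesion receptor Cd44 by 0.69, and the Notch target Hes1 fell by 0.83.

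B cell identity as a list did not pass (mean -0.28, adjusted p = 0.0655), with 5 of 19 members lower and 1 higher, as also adjusted over the list alone. The inhibitory receptor Cd22 fell by 1.43 and Cd24a by 1.09, and the kinase Syk rose by 0.85. With the fibroblast list change as a covariate Cd24a was at 0.01 (limma, adjusted p = 0.984) and the B cell identity list at 0.27. Precursor B cell genes (mean -0.28, median 0.01, adjusted p = 0.384) had 3 of 13 members lower, with 1 higher and 5 lower adjusted over the list alone. Vpreb3, a pre-B cell protein, fell by 2.08. Plasma cell genes (mean 0.18, adjusted p = 0.384) had 4 of 13 members higher and 1 lower, with 5 and 1 adjusted over the list alone. Antigen presentation class I (mean 0.12, adjusted p = 0.557) had 5 of 12 members higher and 2 lower. Class II (mean -0.02, with the camera test pointing up, adjusted p = 0.957) had 2 of 13 higher and 2 lower, with the co-stimulator Cd80 at 1.40 and H2-Ob at -1.23. The Bcl2 family (mean 0.13, adjusted p = 0.212) had 5 of 14 higher and 2 lower. These 3 lists had the same counts adjusted over the list alone. The survival protein Bcl2l1 (Bcl-xL) rose by 0.93 and Bcl2 fell by 0.93 (SE 0.21) on its brightest probe set, while 3 of its 5 probe sets had changes above 0.

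Markers of other cell types moved with the treatment. The cultures grew on irradiated NIH 3T3 fibroblasts, and 26 of 27 fibroblast markers rose, 27 adjusted over the list alone, with a mean of 2.07 ± 1.39 (SD, n = 14) and a range from 0.03 in lymphoma 1467 to 4.64 in lymphoma 403 (adjusted p = 5.63e-17, and adjusted p = 0.0978 with an estimated correlation). Fibronectin (Fn1) rose by 3.30, the collagen Col1a2 by 3.09 and Timp2 by 2.67. Other genes with the largest rises were the matrix protein Efemp1 at 3.70, the membrane protein Tm4sf1 at 3.42, the peptidase Cpe at 3.40 and the protease Prss23 at 3.25. Macrophage and monocyte markers rose in 13 of 19 members, also 13 adjusted over the list alone, with a mean of 1.35 ± 0.69 (SD, n = 14; adjusted p = 8.89e-08, and adjusted p = 0.0803 with an estimated correlation), among them Ms4a7 at 2.69 and the macrophage receptor Adgre1 at 2.18. Of 11 neutrophil markers 3 rose, also 3 adjusted over the list alone: Lcn2 by 2.74, Mmp8 by 2.55 and S100a8 by 2.12 (list mean 0.75, median 0.06, adjusted p = 0.0412, and adjusted p = 0.250 with an estimated correlation). T cell (mean 0.10, median -0.02, adjusted p = 0.803), NK cell (mean -0.02, median 0.01, adjusted p = 0.957), erythroid (mean -0.07, adjusted p = 0.557) and endothelium markers (mean -0.10, adjusted p = 0.341) did not pass. Their members gave 1 higher of 16, 1 lower of 12, 1 lower of 6 and 2 lower of 12, and 1, 0, 0 and 2 adjusted over the list alone.

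**Figure D2:**
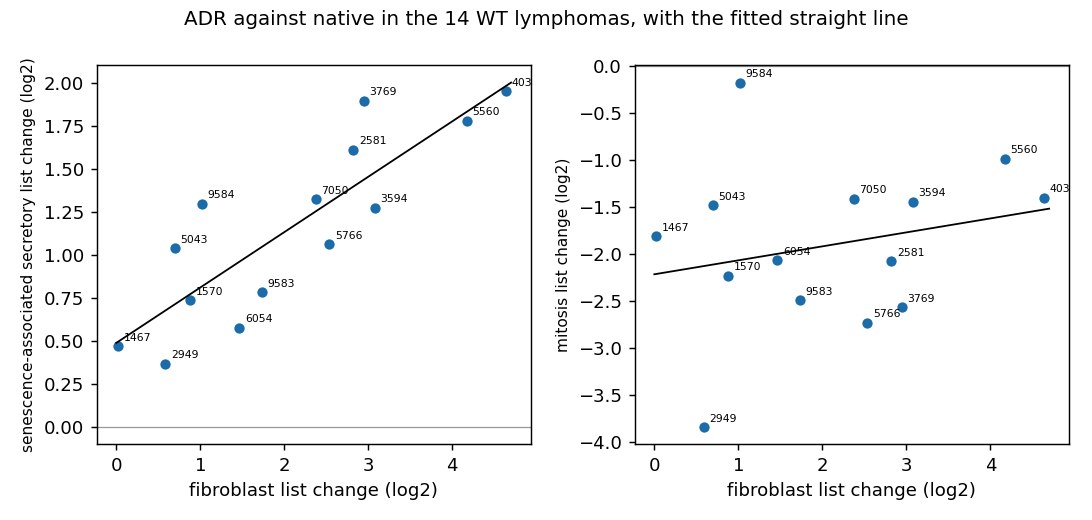
Change of the secretory list (left) and of the mitosis list (right) under ADR, in log2 units, against the change of the fibroblast list in the same lymphoma. Each point is 1 of 14 WT lymphomas with its number, and the line is the fitted straight line, which meets a fibroblast change of 0 at 0.49 for the secretory list and at -2.22 for the mitosis list.

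With the fibroblast list change as a covariate, an alternative added after seeing the data, 2064 genes were called in WT, 1286 of them among the 5489, and Cxcl5 had a log2 change of -0.04. This fit used the 14 WT differences alone and tested the fitted change at a fibroblast list change of 0. That is the low end of the range, where lymphoma 1467 stood at 0.03. Calls can end there through lower precision too, so the smaller count does not measure what feeder RNA explains. Across the 14 lymphomas the mitosis list change was set against 6 other changes, and none passed a permutation test. The closest was the secretory list, with Pearson r = 0.452 (p = 0.106, adjusted p = 0.582) and Spearman rho = 0.455 (p = 0.105, adjusted p = 0.63), and r = 0.303 without lymphomas 2949 and 9584. Of the genes named, Cd44, Cd80, Syk and Timp2 each had 1 probe set below 0, the lowest at -0.24 for Syk.

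In the 5 Suv39h1- lymphomas, which the labels call non-senescent after ADR, few single genes passed the test. Prr32 fell by 0.59 (SE 0.10, adjusted p = 0.0208, lower in 5 of 5 lymphomas), as did 4930555B11Rik, by 0.82 (SE 0.13, adjusted p = 0.0208), a gene chosen for mention after its values were seen. Both genes make up the 2 calls, beside 1885 genes at an unadjusted p under 0.05. With the alike lymphomas counted once 1 gene was called, and Prr32 was at -0.62 (adjusted p = 0.0507). On simulated data, with noise independent between genes and of equal spread in all groups, a log2 change of 0.5 was recovered for 37.3% of genes in this comparison and for 71.6% in WT. That simulation called 150 genes in this comparison. With 2 real calls the adjusted threshold is stricter, so 37.3% is too high here. Cdkn1a had a log2 change of 0.65 (SE 0.34, adjusted p = 0.512) and was higher in 5 of 5 lymphomas. Mki67 was at -0.89 (SE 0.40, adjusted p = 0.433), Lmnb1 at -0.29 (SE 0.32, adjusted p = 0.816), Myc at 0.35, Bcl2 at -0.21 and Cdkn2a at -0.60 (SE 0.76), none of which passed.

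At the level of lists, 10 passed the camera test in Suv39h1- lymphomas. Lysosome (mean 0.29 ± 0.13, SD, n = 5; adjusted p = 9.29e-10), p53 targets (0.35, adjusted p = 6.47e-07), Myc targets (0.13), antigen presentation class I (0.18) and fibroblast markers (0.28) were higher. Mitosis (-0.58 ± 0.79, SD, n = 5; adjusted p = 6.47e-07), replication (-0.34), dna repair (-0.43), glycolysis (-0.27) and cholesterol synthesis (-0.35) were lower. None of their members was called over all genes, and 1 dna repair gene was lower adjusted over the list alone. With an estimated correlation none of these 10 held, and the lowest was adjusted p = 0.674 with an estimated correlation. Without the block the fit called 11 genes in place of 2, and lymphoma 4936 moved against the other 4 in mitosis, at 0.74. Its native array had the lowest native mitosis level, at 8.41 (others 9.28 to 9.40), and its ADR array the highest under ADR, at 9.15 (others 8.03 to 8.69). The 3′ minus 5′ difference of Gapdh, a mark of RNA quality, was higher under ADR in 5 of 5 lymphomas (mean 0.326 against 0.249, exact p = 0.0625, the smallest that 5 lymphomas allow, adjusted p = 0.219 over 21 tests of control signals).

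**Figure D3:**
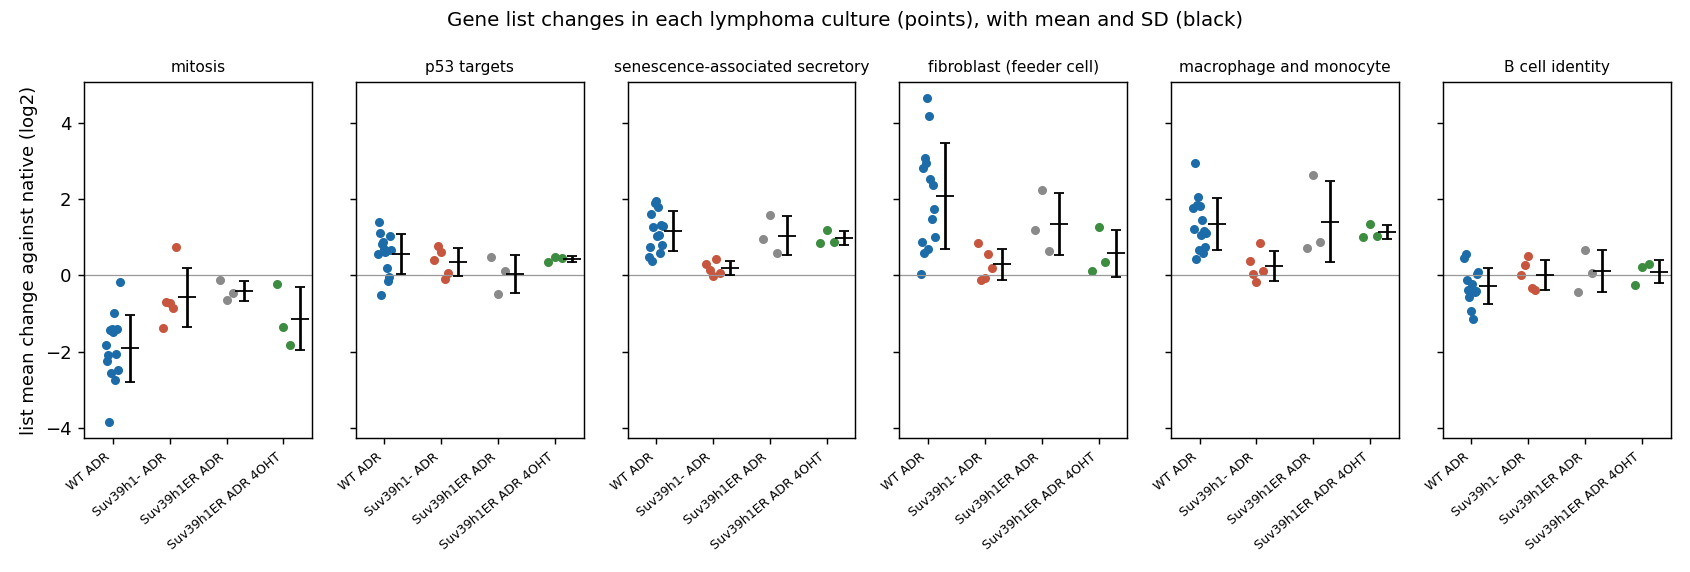
Mean log2 change of 6 gene lists against the native array of the same culture (vertical axis), for WT ADR, Suv39h1- ADR, Suv39h1ER ADR and Suv39h1ER ADR 4OHT. Points are cultures (14, 5, 3 and 3), and black marks give the mean and SD, which for mitosis were -1.91 ± 0.88 in WT and -0.58 ± 0.79 in Suv39h1- lymphomas. Of the Suv39h1ER points, the libraries labelled SuvER-4936 ADR and SuvER-4146 ADR 4OHT did not match their own culture.

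Whether the response differs by genotype was tested as the difference between both responses. The difference, WT response minus Suv39h1- response, passed for 62 genes, 34 above 0 and 28 below. It was below 0 for the division genes Bub1b (-1.67, SE 0.35, adjusted p = 0.046) and Plk1 (-1.62, SE 0.34, adjusted p = 0.046), and for Dut, which clears dUTP (-1.48), the histone H2ax (-1.28), the polymerase subunit Pold2 (-1.18), the potassium channel Kcnk5 (-1.45), Stard4 (-1.16) and Uqcrfs1 (-0.48). The differences above 0 were led by the neutrophil gene Lcn2 (3.08, SE 0.64, adjusted p = 0.046), Ms4a7 (2.64), the galectin Lgals3 (2.19), Ahnak2 (1.96), the stress factor Atf3 (1.96), Cpeb2 (1.60) and Sqstm1 (1.10). Not passing were Lmnb1 (-1.33, adjusted p = 0.0902), Myc (-1.14, adjusted p = 0.0902), Mki67 (-1.42, adjusted p = 0.122), Cdkn1a (0.46, adjusted p = 0.544), Bcl2 (-0.72, adjusted p = 0.332) and Cdkn2a (0.61, adjusted p = 0.749).

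By the exact permutation test over 11628 splits, 12 of 31 lists differed between genotypes. The WT change was lower for mitosis (difference -1.33), replication (-0.91), dna repair (-0.88) and oxidative phosphorylation (-0.24), and higher for the secretory list (0.98), NF-kB (0.71), lysosome (0.55), autophagy (0.34), macrophage (1.11) and neutrophil markers (0.65), with adjusted p = 0.0267 for the secretory list and 0.0325 for the others. Fibroblast markers (1.79, adjusted p = 0.0347) and the Wnt and stem cell list (0.18, adjusted p = 0.0396) were also higher. By the median over members 9 of these 12 lists passed, and autophagy, fibroblast and neutrophil markers did not. The difference did not pass for p53 targets, at 0.21 (exact p = 0.419, adjusted p = 0.541), or for interferon, at 0.87 (exact p = 0.0450, adjusted p = 0.0930).

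Tested by camera, 17 lists passed for the difference of responses. Adjusted over the list alone, 31 of 35 mitosis genes, 28 of 35 replication genes and 13 of 17 dna repair genes were lower and 21 of 27 fibroblast markers, 11 of 39 secretory genes, 7 of 29 lysosomal genes and 5 of 27 interferon genes were higher, and the lowest value of any list was adjusted p = 0.176 with an estimated correlation. Across genes, which are not independent replicates, WT and Suv39h1- changes had r = 0.496, and 4035 of the 5489 genes called in WT (73.5%) had the same sign in Suv39h1- lymphomas, against 60.6% of all genes. For single Suv39h1- lymphomas r with the WT response was 0.549 (5783), 0.343 (1032), 0.268 (7890), 0.106 (9250) and -0.063 (4936). The 62 calls fell to 13 without the block, to 0 without Suv39h1- lymphoma 1032 or 4936 (limma, with 2936 and 2784 genes at an unadjusted p under 0.05), to 1 without 9250, to 1 with the fibroblast list change as a covariate and to 0 with the alike lymphomas counted once (limma, with 3317 at an unadjusted p under 0.05). After median centring 27 of 152 calls were above 0 (17.8%, against 54.8%), and after repeated quantile normalization 38 of 89 (42.7%). The list differences lost all 12 calls without 9250 or 4936, with lowest adjusted p values of 0.0801 and 0.0912. With the alike lymphomas counted once 2 of the 12 passed, the secretory list (1.05) and oxidative phosphorylation (-0.26), and the other 10 had adjusted p values of 0.0568 to 0.0757.

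The Suv39h1ER cultures asked whether activating Suv39h1 changes the ADR response of deficient cells. No array holds 4OHT without ADR or 4OHT in cells without the fusion. Effects of 4OHT itself therefore cannot be told apart from those of Suv39h1. Of the 9 Suv39h1ER arrays, the libraries labelled SuvER-4146 ADR 4OHT and SuvER-4936 ADR matched no other array of their culture over 200 probe sets that mark a lymphoma. Their highest correlations within the culture were -0.122 and -0.292, whereas the lowest of 19 WT and Suv39h1- pairs was 0.469. SuvER-4936 ADR had correlations of 0.656 and 0.722 with the native and ADR arrays of Suv39h1- lymphoma 4936, while the other 2 SuvER-4936 arrays had 0.754 to 0.885 with SuvER-5043, whose own arrays had 0.751 to 0.887 with each other. Xist, the RNA of the inactive X chromosome, was at 11.5 in SuvER-4936 ADR and at 11.74 and 11.43 in Suv39h1- 4936, against 5.86 and 6.27 in the other 2 SuvER-4936 arrays and 6.18 to 6.64 in SuvER-5043. In SuvER-4146 Xist was at 9.60 native and 9.06 under ADR, against 6.11 under ADR with 4OHT. These values leave open whether the 3 cultures are 3 separate lymphomas, so n = 3 counts cultures as labelled, and SDs and p-values are too small if a lymphoma entered more than once. All Suv39h1ER values include all 9 arrays unless stated. Without both unmatched libraries SuvER-4146 and SuvER-5043 hold an ADR and a native array, SuvER-4936 and SuvER-5043 an ADR 4OHT and a native array, and 1 culture, SuvER-5043, both an ADR and an ADR 4OHT array. With SuvER-5043 as the single culture each arm is 1 array, so the spread comes from WT and Suv39h1- lymphomas alone and the lone arrays are assumed to vary like those.

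Adding 4OHT to ADR changed 26 genes, 8 higher and 18 lower. The largest rises were Eqtn (2.88, SE 0.55, adjusted p = 0.0485), the semaphorin receptors Plxna3 (1.09) and Plxnb2 (0.92), the scaffold Iqgap1 (1.00), the phosphatase subunit Ppp1r12c (0.76 on 1 probe set and -0.10 on the other) and Nat14 (0.74). Falling were Lgals3 (-2.45, SE 0.47, adjusted p = 0.0485), Zc4h2 (-1.39), the histone chaperone Asf1a (-1.30 on 1 probe set and 0.02 on the other), Jade1 (-1.27), the centriole protein Poc1b (-1.17) and Znrd1 (-1.14), each in 3 of 3 cultures as labelled. Only in SuvER-5043 do both arrays of this comparison match their culture, so the other pairs may hold differences between lymphomas. Cdkn1a (0.89, adjusted p = 0.407), Cdkn2a (-2.68, SE 0.98, adjusted p = 0.243), Mki67 (-0.51, adjusted p = 0.771), Lmnb1 (-0.75, adjusted p = 0.494), Bcl2 (0.60) and Myc (0.44) did not pass.

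Of the lists, 13 passed in this comparison. Replication (-0.68 ± 0.52, SD, n = 3; adjusted p = 1.14e-10), mitosis (-0.72 ± 0.64, SD, n = 3; adjusted p = 5.47e-07), dna repair (-0.65), oxidative phosphorylation (-0.31 ± 0.05, SD, n = 3; adjusted p = 1.14e-10), Myc targets (-0.26) and fibroblast markers (-0.77) were lower with 4OHT. Lysosome (0.35, adjusted p = 1.46e-07), p53 targets (0.39), NF-kB (0.22), interferon (0.36), cholesterol synthesis (0.48), class I (0.33) and the Bcl2 family (0.27) were higher. Adjusted over the list alone, 11 of 25 oxidative phosphorylation genes and 6 of 35 replication genes were lower and 5 of 29 lysosomal genes higher. The lowest value was adjusted p = 0.196 with an estimated correlation. Without both unmatched libraries the fibroblast list was at -0.14 (adjusted p = 0.934), and in SuvER-5043 as the single culture at -0.26. Without both libraries p53 targets (0.22), interferon (0.25), Myc targets (-0.05), class I (-0.08) and the Bcl2 family (0.20) did not pass either, whereas mitosis (-1.32), replication (-1.10), dna repair (-1.13), lysosome (0.63), NF-kB (0.65) and cholesterol synthesis (0.86) moved further from 0. Only 1 complete pair, that of SuvER-5043, is left there, and with it as the single culture the same lists were at -1.37, -1.25, -1.14, 0.64, 0.69 and 0.47. Without the block 16 genes were called, without both unmatched libraries 3 (1 of them, Iqgap1, among the 26), without SuvER-4936 1 (0 of the 26), and with SuvER-5043 as the single culture, 1 array against 1 on the spread of the other genotypes, 0 (limma, with 676 genes at an unadjusted p under 0.05). The difference between the 3′ and 5′ Actb probe sets, a mark of RNA quality, was higher with 4OHT in 3 of 3 cultures (mean 0.90 against 0.62). After median centring 3 of 22 calls were higher (13.6%, against 30.8%).

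Under ADR without 4OHT, 23 genes changed in Suv39h1ER cultures, 16 higher and 7 lower. The lysozymes Lyz1 (6.54, SE 0.83, adjusted p = 0.000234) and Lyz2 (5.38, SE 0.81, adjusted p = 0.00297), made by macrophages and neutrophils, rose most, followed by Mmp13 (4.77), Cxcl2 (4.48), Lgals3 (4.01), Lcn2 (3.96), the chemokine Ccl3 (3.48) and the myeloid growth factor Csf2 (2.16). The linker histone H1f4 fell by 2.84 (SE 0.31, adjusted p = 3.71e-05), Mib2 by 1.25, Mpnd by 0.92, Accs by 0.75, the deubiquitinase Usp48 by 0.72 and the phosphatase Ptpn2 by 0.74, although 2 of the 4 Ptpn2 probe sets had changes above 0. Without both unmatched libraries 4 of these 23 were called, among them Lyz1, Lgals3 and H1f4, and Lyz2, Mmp13, Cxcl2, Lcn2, Ccl3 and Csf2 were not. Mki67 (-1.08, adjusted p = 0.400) and Cdkn1a (-0.19, adjusted p = 0.918) did not pass. The 18S control signal was lower under ADR than native in 3 of 3 cultures (mean 8.33 against 9.56), as was the difference between the 3′ and 5′ Actb probe sets (0.62 against 1.11), each with an exact p of 0.25, the smallest that 3 cultures allow.

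Macrophage markers (1.41 ± 1.06, SD, n = 3; adjusted p = 1.39e-06), fibroblast markers (1.34 ± 0.82, SD, n = 3; adjusted p = 4.10e-07), the secretory list (1.04 ± 0.50, SD, n = 3; adjusted p = 2.99e-08), NF-kB (0.75), interferon (0.53), lysosome (0.35) and Myc targets (0.24) were higher. Cholesterol synthesis (-0.67, adjusted p = 3.01e-07), dna repair (-0.47), mitosis (-0.42), glycolysis (-0.34), replication (-0.26) and H3K9 genes (-0.06) were lower. Adjusted over the list alone, 8 of 39 secretory genes and 6 of 19 macrophage markers were higher. The lowest value over these 13 lists was adjusted p = 0.388 with an estimated correlation. Single cultures had macrophage changes of 0.73 (SuvER-4146), 2.63 (SuvER-4936) and 0.87 (SuvER-5043), and without both unmatched libraries the list was at 0.84 (adjusted p = 0.000255), mitosis at -0.25 and interferon at 0.32. NF-kB (0.34), lysosome (0.15), glycolysis (-0.18), replication (-0.12) and H3K9 genes (-0.06) then did not pass. With SuvER-5043 as the single culture the secretory list was at 0.58 and fibroblast markers at 0.62, interferon at 0.07, cholesterol synthesis at -0.28 and Myc targets at 0.12. Without the block 2 genes were called, without SuvER-4936 4, and with SuvER-5043 as the single culture 3, on the spread of the other genotypes. After repeated quantile normalization 17 of 35 calls were higher (48.6%, against 69.6%).

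With ADR and 4OHT together, 537 genes differed from native Suv39h1ER cells, 251 higher and 286 lower. Lyz1 (6.94, SE 0.83, adjusted p = 8.14e-05), Mmp13 (6.07), Lyz2 (5.58), Ccl3 (4.75), Wfdc17 (4.43) and Lcn2 (4.29) rose most, and the lysosomal genes Lamp1 (1.21) and Tpp1 (1.30) and the receptor Cd44 (1.32) rose too. H1f4 fell by 3.03 (SE 0.31, adjusted p = 5.42e-06), Rasgrp2, an activator of Rap1, by 2.82, Cox6a2 by 2.77, the kinetochore proteins Cenpp and Ska1 by 2.24 and 2.15, the repair helicase Rad54b by 2.13, the thymidine kinase Tk1 by 1.78, Gins1 by 1.69 and Aurkb by 1.67. Mki67 (-1.59, adjusted p = 0.0957) and Cdkn1a (0.70, SE 0.43) did not pass. Ska1 and Cd44 each had 1 probe set on the other side of 0, at 0.01 and -0.08.

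Replication (-0.93 ± 0.60, SD, n = 3; 6 of 35 members lower, 25 adjusted over the list alone), mitosis (-1.14 ± 0.83, SD, n = 3; 1 of 35, and 16), dna repair (-1.12 ± 0.63, SD, n = 3; 5 of 17, and 16), oxidative phosphorylation (-0.25) and H3K9 genes (-0.17) were lower. Lysosome (0.70 ± 0.12, SD, n = 3; 8 of 29 members higher, 15 adjusted over the list alone), NF-kB (0.97), the secretory list (0.97), interferon (0.89), macrophage markers (mean 1.13, median 0.12), fibroblast markers (0.58), p53 targets (0.43), Wnt and stem cell genes (0.28), the Bcl2 family (0.23) and autophagy (0.20) were higher. Of these 15 lists the lowest value was adjusted p = 0.0865 with an estimated correlation. Without both unmatched libraries interferon was at 0.57, and with SuvER-5043 as the single culture mitosis was at -1.83, replication at -1.55, autophagy at 0.34 and fibroblast markers at 0.36. Without the block 267 genes were called, without SuvER-4936 90 (77 of them among the 537), without SuvER-4146 326, without SuvER-5043 162 and with SuvER-5043 as the single culture 11, on the spread of the other genotypes. The 18S control signal was lower than native in 3 of 3 cultures (mean 8.78 against 9.56). Across genes, WT changes under ADR had r = 0.603 with this comparison and r = 0.515 with Suv39h1ER ADR vs native, a difference that was not tested. Both use the same native Suv39h1ER arrays. The difference of responses, WT minus Suv39h1-, had r = 0.117 with Suv39h1ER ADR 4OHT vs ADR. Of its 62 called genes 48 had the same sign there (77.4%), against 55.8% of all genes. For single cultures r was 0.127 (SuvER-4146), -0.104 (SuvER-4936) and 0.339 (SuvER-5043).

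Before treatment, WT and Suv39h1- lymphomas differed in 198 genes, 173 higher and 25 lower in WT. Higher in WT were Bcl2 (2.18, SE 0.27, adjusted p = 0.000103), the galectin Lgals9 (2.03), the B cell receptor component Cd79a (2.01, SE 0.23, adjusted p = 4.69e-05), Tgfb1 (1.64 on 1 probe set and -0.05 on the other), the corepressor Tle5 (1.60), Mlf2 (1.55, SE 0.11, adjusted p = 2.02e-07), the tetraspanin Cd37 (1.53), the glycolytic enzymes Pfkl (1.33) and Pkm (0.97), the class II chaperone Cd74 (1.02) and the H3K9 methyltransferase Ehmt2 (0.88). Lower were Il6ra (-0.92), Arglu1 (-0.91), Zfp329 (-0.82), Ift20 (-0.77), the kinase Pik3cd (-1.96) and the histone chaperone Hira (-0.80). For Pik3cd 3 of 6 probe sets were called in the opposite direction, and for Hira 3 of 4 had changes above 0. Zfp329 and Pfkl each had 1 of 3 probe sets on the other side of 0, at 0.06 and -0.01. Myc (0.10), Mki67 (-0.08), Cdkn1a (0.59), Cdkn2a (-1.70, adjusted p = 0.512) and Lmnb1 (-0.66, adjusted p = 0.490) did not pass.

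B cell identity genes were higher in native WT (mean 0.39, 3 of 19 members, also 3 adjusted over the list alone, adjusted p = 8.94e-05, and adjusted p = 0.196 with an estimated correlation), as were glycolysis (0.32), antigen presentation class I (0.34), the Bcl2 family (0.29), lysosome (0.15), autophagy (0.12) and mitosis (0.11), for which the lowest value was adjusted p = 0.155 with an estimated correlation. The 18S control signal, a mark of RNA and labelling, also differed between the genotypes (exact permutation p = 8.6e-05, the smallest these splits can give). It had a mean of 7.66 in native WT and 8.64 in native Suv39h1- arrays, and the 3′ minus 5′ differences of Gapdh and Actb were lower in WT too (0.0766 against 0.249 and 0.589 against 0.85). Without Suv39h1- lymphoma 1032 the native comparison called 316 genes in place of 198. With the alike lymphomas counted once Il6ra (-0.79), Hira (-0.66), Pkm (0.86) and Cd74 (0.99) did not pass, nor did the glycolysis (0.17), Bcl2 family (0.21), autophagy (0.05) and mitosis (0.10) lists.

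After ADR, 2293 genes differed between the genotypes, 1146 higher and 1147 lower in WT. Lmnb1 (-1.99, SE 0.24, adjusted p = 7.11e-05), the division genes Trip13 (-1.84), Aspm (-1.81), Depdc1a (-1.80), Bub1b (-1.42) and Mki67 (-1.50, SE 0.41, adjusted p = 0.0231), Pola1 (-1.79), Chek1 (-1.47) and the sterol genes Idi1 (-1.82) and Stard4 (-1.77) were lower in WT. Higher in WT were Lcn2 (3.47), Ms4a7 (2.82), the lipase Lpl (2.81), the collagen Col1a1 (2.42), Plod2 (2.38), the antiviral Ifitm3 (2.38), Tgfb1 (1.98), Sqstm1 (1.82, SE 0.27, adjusted p = 0.000463), the protease Ctsd (1.58), Tnf (1.53), the NF-kB subunit Relb (1.29), Phlda3 (1.20), Mdm2 (1.07), Cdkn1a (1.06, SE 0.32, adjusted p = 0.0361) and Bcl2 (1.46). Pik3cd (-1.89), Hira (-1.24) and Ehmt2 (0.73) had differed before treatment too. Of their probe sets, 3 of 6 for Pik3cd and 2 of 4 for Hira were on the other side of 0, as was 1 of 2 for Tgfb1, at -0.10. Myc (-1.04, adjusted p = 0.0737) and Cdkn2a (-1.09, adjusted p = 0.355) did not pass.

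Mitosis (mean -1.22, 25 of 35 members lower, 32 adjusted over the list alone), replication (-0.84, 21 of 35, and 28), dna repair (-0.90, 12 of 17, and 14), cholesterol synthesis (-0.81, 9 of 16, and 11), Myc targets (-0.51, 10 of 31, and 20), oxidative phosphorylation (-0.25, 10 of 25, and 14) and H3K9 genes (-0.20) were lower in WT. NF-kB (0.88, 6 of 18, and 8), interferon (0.94, 3 of 27, and 5), the secretory list (0.97, 4 of 39, and 4), lysosome (0.71, 7 of 29, and 11), autophagy (0.46, 8 of 23, and 13), unfolded protein stress (0.52, 5 of 23, and 8), the Bcl2 family (0.42), fibroblast markers (1.62, 2 of 27, and 13) and macrophage markers (1.12, 1 of 19, and 1) were higher. The lowest value was adjusted p = 0.242 with an estimated correlation. The 18S control signal differed here as well, at 7.78 in WT and 8.72 in Suv39h1- arrays (exact permutation p = 0.000774, adjusted p = 0.00542 over 21 tests of control signals), as did the 3′ minus 5′ difference of Actb, at 0.562 and 0.868 (exact permutation p = 0.00989, adjusted p = 0.0415). For Gapdh it was 0.179 and 0.326 (exact permutation p = 0.189). Median centring moved the median of all genes from 0.04 to -0.07 and left 634 of 2926 calls higher (21.7%, against 50.0%), with no list or named gene changing sign. Without Suv39h1- lymphoma 9250, 4936 or 7890 the comparison called 1227, 1365 and 1369 genes in place of 2293, and with the alike lymphomas counted once 939, 923 of them among the 2293. Lcn2, Col1a1, Plod2, Ifitm3, Aspm, Depdc1a, Phlda3, Mdm2, Tnf, Bcl2, Cdkn1a and Mki67 (adjusted p = 0.0533 to 0.162) and the Bcl2 family list (0.37, adjusted p = 0.084) then did not pass.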

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

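Chosen only after the result was seen were the tests of the Suv39h1ER libraries, those of the 18S and other control signals, the counts with alike lymphomas counted once, the tests of the macrophage list and of mitosis against B cell identity, and every model of the secretory list but the straight line.

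Groups of 4 to 10 samples were tested for a sample far from the rest, which here are those of the 5 Suv39h1- lymphomas. The array of lymphoma 1032 under ADR had a median of 4.07, where the other 4 lay between 4.32 and 4.36. Lymphoma 4936 was above 0 under ADR where the other 4 were below, with list changes of 0.77 for replication (others -0.87 to -0.46), 0.76 for dna repair (others -0.98 to -0.54) and 0.27 for oxidative phosphorylation (others -0.12 to -0.02). Both of its arrays stood apart in mean mitosis level. The native array was at 8.41 (others 9.28 to 9.40) and the ADR array at 9.15 (others 8.03 to 8.69). Its mitosis change thus includes a low native level, and the cause was not tested. Lymphoma 1032 stood apart in T cell markers, at -0.32 (others -0.07 to 0.00), and in neutrophil markers, at 0.65 (others -0.20 to 0.03). Of 39 groups of values tested, 6 had such a sample, and chance gives about 5%. The WT and Suv39h1ER groups were too large or too small for this test. Among WT ADR arrays 1570 had a 3′ minus 5′ difference of 0.907 for Gapdh (others 0.011 to 0.437) and 1.12 for Actb (others 0.382 to 0.767), and without it 5330 genes were called in WT. The array labelled SuvER-4146 ADR 4OHT had signals of 12.01 and 13 for the bacterial control transcripts lys and dap, where the other 2 of its group had 4.905 and 5.427, and 9.1 and 9.332.

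The response to ADR differed between WT and Suv39h1- lymphomas by a test of the difference itself in 12 lists and 62 genes. No list passed without lymphoma 9250 or 4936, and 2 did with the alike lymphomas counted once. The gene count (limma) was 0 without 1032 or 4936 or with the alike lymphomas counted once, and 1 with the fibroblast list change as a covariate. Fibroblast markers are among the 12 lists. For lists that moved with them, such as secretory and lysosome, feeder RNA was therefore not separated from genotype. The list differences, WT minus Suv39h1-, were -1.33 for mitosis, -0.91 for replication, -0.88 for dna repair, -0.24 for oxidative phosphorylation, 1.79 for fibroblast, 1.11 for macrophage and 0.65 for neutrophil markers, 0.98 for the secretory list, 0.71 for NF-kB, 0.55 for lysosome, 0.34 for autophagy and 0.18 for Wnt and stem cell genes. Of 10143 probe sets with no single gene name, which entered no comparison of genes, 51 were array controls and left out, and among the other 10092 1095 (10.9%) changed under ADR in WT, 462 higher and 633 lower.

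Fibroblast and secretory genes rose together in WT lymphomas under ADR, and more RNA from the irradiated feeder fibroblasts is a candidate explanation. Changes of pairs of fibroblast markers had a median correlation of 0.76 over the 14 lymphomas, against at most 0.0744 in 100 random sets of genes of the same level, although induction of these genes together in lymphoma cells would give this too; 11 of the 27 markers lay in the upper part of genes in native WT (above the median gene level of 5.42, the highest being Vim at 11.73) and 1 is in another list. At a fibroblast change of 0 the straight line gave a secretory change of 0.489 (95% interval 0.176 to 0.802). With a squared term it was 0.483 (0.00873 to 0.958), and without lymphomas 403 and 5560 0.4656 (0.0671 to 0.864). The macrophage list, with 11 of 19 members above that median level, kept a lower bound of 0.5003. These bounds above 0 go against feeder RNA that moves with the fibroblast markers as the whole cause, but do not exclude it. Error in the fibroblast list change flattens such a line and raises its value at 0, and was not modelled. Feeder genes that rose apart from these markers are not covered. With fibroblast and macrophage changes both in the model the secretory value was 0.216 (-0.188 to 0.619), so RNA of both cell types together stays open, as does a response of the lymphoma cells. Dilution of lymphoma RNA as the whole cause of the mitosis fall is argued against by mitosis minus B cell identity, at -1.63 with an upper bound of -1.028 and below 0 in 13 of 14 lymphomas.

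Of the 9 Suv39h1ER arrays, 2 matched no array of their own culture, the libraries labelled SuvER-4146 ADR 4OHT (highest r -0.122) and SuvER-4936 ADR (highest r -0.292), where 19 WT and Suv39h1- pairs had at least 0.469. An effect of ADR or 4OHT on the marking probe sets is argued against by SuvER-5043, whose lowest correlation across the same treatments was 0.751. Arrays of another lymphoma under the culture's name could give these values, but in SuvER-4936 these may be the other 2 arrays, whose lowest r with SuvER-5043 was 0.754 and whose Xist levels were 5.86 and 6.27 (6.18 to 6.64 in SuvER-5043), while SuvER-4936 ADR had a lowest r of 0.656 with Suv39h1- 4936 and Xist at 11.5 (11.43 and 11.74 there). Neither origin is settled. By their highest r, 15 of 171 pairs of lymphomas with different numbers exceeded 0.469, up to 0.924 for WT 5766 and 6054. The values above for SuvER-4936 are lowest r. By that measure only pairs among WT 2949, 5043, 5766 and 6054, and Suv39h1- 7890 with 9250, exceeded 0.469. The lowest r of such a pair reached 0.768, for WT 5766 and 6054. Whether those are separate lymphomas is not shown, so how alike separate lymphomas can be stays open. SuvER-4146 ADR 4OHT matched no array above 0.387, and its Xist level was 6.11, against 9.60 (native) and 9.06 (ADR) in its culture. No biological explanation was tested.

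Genes higher in native WT than in native Suv39h1- lymphomas went with a lower 18S control signal, 7.66 against 8.64 (exact permutation p = 8.6e-05, the smallest these splits can give), and a smaller difference between the 3′ and 5′ Gapdh probe sets, 0.0766 against 0.249. After ADR, where 2293 genes differed, 18S was again lower in WT, 7.78 against 8.72 (exact permutation p = 0.000774). Genotype and array handling cannot be told apart here, because the signal follows the genotype. A difference between the genotypes themselves stays open.

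Other splits of the samples were drawn for each count of called genes. For WT ADR vs native 1 of 100 splits, the real one, gave as many genes (5489, highest other 1869), and for the ADR arrays by genotype 1 of 100 (2293, highest other 11), a share under 0.05. These splits take the lymphomas as labelled for separate units, which the values leave open for some of them. In both other comparisons of WT with Suv39h1- a split other than the real one called more genes. For the difference of responses 2 of 100 gave as many as the real 62 and the other called 102, and the real count was 0 without lymphoma 1032 or 4936 and 1 without 9250, so this count rests on single lymphomas although the share of splits is under 0.05. For the native arrays by genotype 2 of 100 gave as many as the real 198, and the other, which set WT 2949, 5043, 5766 and 6054 and Suv39h1- 1032 apart, reached 1396 (the next highest 37). A count several times the real one points to a structure of the samples, and these 4 WT lymphomas are the ones whose arrays correlated with each other, at 0.556 to 0.924, as highly as those of 1 lymphoma. With them, and likewise Suv39h1- 7890 and 9250, counted once, the native arrays gave 134 genes, the ADR arrays 939 and the difference of responses 0 (limma, 3317 at an unadjusted p under 0.05). Other splits were not drawn for these counts. Splits were too few for a share under 0.05 in Suv39h1- lymphomas (3 of 16, real 2, highest other 8) and in Suv39h1ER cultures (1 of 4 each: 26 and highest other 1 for ADR 4OHT vs ADR, 23 and 0 for ADR vs native, 537 and 7 for ADR 4OHT vs native).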

How the results depend on the processing

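Chosen only after the result was seen were the fits with the fibroblast list change as a covariate, without the 2 unmatched Suv39h1ER arrays, with SuvER-5043 as the single culture, with WT and Suv39h1- arrays alone, and with alike lymphomas counted once. Over 195 gene results and 3872 settings, 3303 kept direction and side of the threshold, 528 lost the call, 9 gained one and 32 reversed. Over 122 list results and 1599 settings the numbers were 1322, 253, 8 and 16, and 73 of 143 gene counts and 77 of 94 list counts stayed within 1.5 times. Unless stated, the cause was not tested. Array number limits precision, and signal over background was not used here. The fibroblast list has no value under its own covariate, which fixes it at 0.

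With the pairing dropped, the counts without the block were 4656 for WT, 11 for Suv39h1- (2 with it), 13 for the difference of responses (62), 16 for Suv39h1ER ADR 4OHT vs ADR (26), 2 for Suv39h1ER ADR vs native (23) and 267 for ADR 4OHT vs native (537). Of named genes 36 calls ended without the block and of lists 7, and no other call changed. With the block as a random effect the counts were 84 for Suv39h1-, 142 for the difference and 60 for ADR 4OHT vs ADR. All 47 arrays in 1 fit with the lymphoma as a random effect, which changes the arrays entered as well, gave 3502 for the genotypes under ADR (2293). With equal culture numbers as 1 block they were 0 for Suv39h1- (limma, 2004 at an unadjusted p under 0.05), 233 for the difference, 1 for ADR 4OHT vs ADR and 997 for ADR 4OHT vs native. With the compared groups alone they were 0 for Suv39h1- (1448 unadjusted), 40 for the difference, 0 for ADR 4OHT vs ADR (2077 unadjusted), 2 for ADR vs native and 12 for ADR 4OHT vs native.

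Every probe set tested gave 30 for the difference, 189, 108 and 778 for ADR 4OHT vs ADR, ADR vs native and the native genotypes (198). Genes above the median level gave 0 for Suv39h1- (598 unadjusted), 122 for the difference and 43 for ADR 4OHT vs ADR. Trend and robust gave 12, 28 and 7 for the same. Array weights gave 0 for Suv39h1- (1493 unadjusted), 12 for the difference, 222, 57 and 970 for the Suv39h1ER comparisons and 109 for native genotypes. Centring gave 152 for the difference and quantile normalization 35 for ADR vs native, and both gave 1 of 3 Suv39h1- calls higher (33.3%, against 0 of 2). After quantile normalization 851 of 2126 calls in the ADR arrays by genotype were higher, against 1146 of 2293. The fibroblast covariate gave 2064 for WT and 1 for the difference. WT and Suv39h1- arrays alone gave 0 for Suv39h1- (1918 unadjusted). Alike lymphomas counted once gave 5266 for WT, 1 for Suv39h1-, 0 for the difference (3317 unadjusted), 134 for native and 939 for ADR genotypes, with fewer lymphomas in the fit. Without the 2 unmatched arrays the counts were 102 for the difference, 3 for ADR 4OHT vs ADR and 4 for ADR vs native, and with SuvER-5043 alone, where each arm is 1 array assumed to vary like the WT and Suv39h1- arrays, 0 (limma, 676 unadjusted), 3 and 11 for the Suv39h1ER comparisons, which shows nothing about the spread between Suv39h1ER cultures.

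Leaving out each lymphoma gave 4920 to 5694 in WT. It gave 0 to 12 for Suv39h1-, with 0 without 4936 (2342 unadjusted), 1 without 1032, 4 without 9250 and 12 without 5783 or 7890. The difference had 0 to 119, with 0 without 1032 or 4936 (2936 and 2784 unadjusted), 1 without 9250 and 119 without 5783. Leaving out SuvER-4146, 4936 and 5043 gave 2, 1 and 56 for ADR 4OHT vs ADR, 44, 4 and 109 for ADR vs native, and 326, 90 and 162 for ADR 4OHT vs native. Native genotypes had 138 to 316 (316 without 1032), and ADR genotypes 1227 to 3389 (1227 without 9250, 1365 without 4936, 1369 without 7890, 3389 without 1032).

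With an estimated correlation 0 lists were called in each of 8 comparisons (camera, against 19, 10, 17, 13, 13, 15, 7 and 16). The fibroblast covariate called 12 lists in WT and 10 for the difference. Fry called 0 in Suv39h1-, 1 in ADR 4OHT vs ADR, 2 in ADR vs native, 8 in ADR 4OHT vs native and 2 in native genotypes. Native genotypes had 4 with the mean of probe sets, and ADR vs native 7 with SuvER-5043 alone, under the same assumption.

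Lists that turned in WT were, by the median, senescence arrest (0.0803), precursor B cell (0.00805), T cell (-0.0159) and NK cell (0.00792), and, with the fibroblast covariate, Myc targets (0.37, which passed, adjusted p = 1.61e-05), class II (0.0992), B cell identity (0.27) and endothelium (0.00287). With that covariate the list T cell in WT ADR vs native was -0.0917 and the list NK cell in WT ADR vs native 0.0241. The list antigen presentation class II in WT ADR vs native was 0.0405 with equal numbers as 1 block and 0.127 with alike lymphomas counted once. In the difference of responses Myc targets were 0.12 and B cell identity 0.20 with the covariate. The list antigen presentation class I in Suv39h1ER ADR 4OHT vs ADR was -0.0779 without the unmatched arrays, and H3K9 genes in ADR vs native 0.00688 over every probe set.

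With the covariate the gene Cxcl5 in WT ADR vs native turned to -0.0419, the gene Cd24a in WT ADR vs native to 0.0134, the gene Myc in WT ADR vs native to 0.119 and the gene Cdkn2a in WT ADR vs native to -0.00635. The last was also -0.00520 after quantile normalization, -8.89e-05 after centring, -0.0504 with array weights and -0.0508 to 0.0663 over lymphomas left out (below 0 without 1570, 2581, 2949 or 3769). The gene Cdkn2a in Suv39h1- ADR vs native was 0.157 with equal numbers as 1 block and -0.941 to 0.0264 over lymphomas left out, and the gene Cdkn2a in WT response minus Suv39h1- response -0.0903 and -0.0128 to 0.954 (both turned without 5783). Bcl2 in the difference was 0.10 over the mean of probe sets. The gene Bcl2 in Suv39h1ER ADR 4OHT vs ADR was -0.54 without the unmatched arrays, -0.14 with SuvER-5043 alone and -0.00229 to 0.97 over cultures left out (lowest without 4936), and the gene Mki67 in Suv39h1ER ADR 4OHT vs ADR -0.99 to 0.000963 (highest without 5043). In ADR vs native Ptpn2 was 0.14 over the mean of probe sets, and Cdkn1a 0.49 with equal numbers as 1 block, 0.36 with weights, 0.45 without the unmatched arrays and -0.83 to 0.49 over cultures left out (above 0 without 4936). The mean of probe sets gave 0.0425 for the gene Pik3cd in WT vs Suv39h1- native and 0.0310 for the gene Hira in WT vs Suv39h1- native, where Myc was -0.30 to 0.39 (below 0 without 5783 or 1032), and the gene Mki67 in WT vs Suv39h1- native was -0.28 to 0.0381 (above 0 without 7890 or 9250). The gene Pik3cd in WT vs Suv39h1- ADR was 0.00195 over the mean of probe sets.

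List differences by the exact permutation test were weaker by the median for autophagy (0.18, adjusted p = 0.143), fibroblast (1.83, adjusted p = 0.0659) and neutrophil markers (0.16, adjusted p = 0.197). Over lymphomas left out they were -1.04 to -0.64 for replication, -1.01 to -0.58 for dna repair, 0.92 to 1.04 for secretory, 0.62 to 0.82 for NF-kB, 0.51 to 0.59 for lysosome, 0.27 to 0.38 for autophagy, -0.27 to -0.17 for oxidative phosphorylation, 0.14 to 0.22 for Wnt, 1.69 to 1.93 for fibroblast, 1.01 to 1.26 for macrophage and 0.57 to 0.78 for neutrophil markers. The list difference between genotypes, mitosis, ran from -1.53 to -0.9996. With alike lymphomas counted once they did not pass for mitosis (-1.19), replication (-0.95), dna repair (-0.86), NF-kB (0.78), lysosome (0.61), autophagy (0.39), Wnt (0.20), fibroblast (1.897), macrophage (1.11) and neutrophil markers (0.67), with adjusted p from 0.0568 to 0.0757. Without 9250 or 4936 none of the 12 passed (lowest adjusted p 0.0801 and 0.0912), without 1032 8 of the 12 and without 7890 10 did. Without lymphomas 2949 and 9584 the mitosis relation turned with p53 targets (-0.16), interferon (-0.17), lysosome (-0.17) and Cdkn1a (-0.29).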
